A study of Mus musculus with 16 samples.

How the data were processed

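RNA was measured in stromal cells sorted from mouse bone marrow as live single cells negative for CD45, Ter119 and CD31 and positive for CD51 and CD140a, per the labels. The mice were Townes sickle mice of 2 genotypes, SS (homozygous for human sickle beta globin) and SA (heterozygous, with 1 sickle and 1 normal human beta globin). Total RNA was taken up with a small-input extraction kit and made into libraries with a low-input kit, per the labels' protocols. The 16 samples are 8 mouse libraries, each sequenced on 2 lanes, and the deposited tables hold 1 column per mouse, so that the replicate was the mouse and n was 4 per genotype. Titles number the mice within a genotype, and no label states further that they are separate animals. If they were not, p-values measure only the spread between these libraries. 1 lane of SS replicate 4 carries SS in its title and SA in its source and mouse group. It was kept in SS, since its title and library number are those of the other lane of that mouse. Titles also carry date-like numbers that fall into 3 sets, 1 of them covering every SA library and the other 2 the SS libraries, so that they cannot be told apart from genotype. What these numbers stand for is not given in the sources used here.

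The authors deposited raw read counts per gene symbol and a second table of normalized signal. The submitters' processing notes name bcl2fastq, STAR, featureCounts and DESeq2 with the builds mm10 and GRCm38, without versions or roles. The annotation and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes cannot be separated, and values of near-identical copies (histone genes, alpha globin genes, Bglap2 and its neighbour) are uncertain. In the deposited signal table each value was the raw count divided by 1 factor per library. The factors ran from 0.953 in SA replicate 1 to 1.13 in SS replicate 4. That table was used for nothing else.

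The count table held 52459 genes, of which 21138 had no count in any library. Total counts per library ran from 24797857 to 31117007. Intervals given for shares are 95% Wilson intervals and floors are 3 counts per library. Both cover counting error only, since reads without molecular identifiers are not independent molecules.

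Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by genotype, TMM factors, robust dispersion estimates and the quasi-likelihood F test, with Benjamini-Hochberg adjustment over the 17316 genes kept and a threshold of 0.05. Adjusted p-values are from this test unless another is named. Expression is given as CPM, the counts scaled by TMM-adjusted library totals, mean ± SD over 4 mice. Fold changes are log2 of SS over SA, with a standard error (SE) taken as the fold change divided by the root of the F statistic. 38 gene lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the lists. Library composition (16 shares or summed CPM values) was compared by a two-sided exact permutation test over the 70 arrangements of 8 libraries, which cannot give a p below 0.0286. Raw totals are the denominator of these shares. Gene positions are from GENCODE M21 on GRCm38, matched by symbol. 91.7% of the table's symbols matched, and 96.5% of those tested. Cyr61 was among those without a match.

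The lists, the tests, the naming rule and most alternatives were fixed before the data were examined. Genes are named as checks of labels and sort (mouse globins, Xist, Y-linked genes, Pdgfra, Itgav, Ptprc, Pecam1), as Cxcl12, Kitl, Angpt1, Vcam1, Tlr4 and Lepr whatever their values, as up to 4 genes per list with the smallest p, and as the genes past the threshold, or if fewer than 12 pass in a direction, those plus enough of the smallest p to make 6. This last part took only genes with a mean of at least 5 CPM and no overlap between genotypes, without unnamed gene models. Some genes that these rules select are not reported here.

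The scripts were tested on simulated counts for the 17316 genes with the means, dispersions and library sizes of these libraries. edgeR recovered 2% of 50 genes changed 2-fold, 34% of those changed 4-fold, 50% at 8-fold and 74% at 16-fold, with 81 calls of which 1 was false. DESeq2 1.42.0 on the same counts recovered 14%, 56%, 82% and 94%, with 191 calls of which 68 were false. A planted list raised in SS was called by camera at an adjusted p of 0.00355, and 0 of 30 random lists were. Genes were simulated independently of each other, so this does not test camera on lists whose genes move together. In the real libraries the estimated correlation within a list ran from -0.05 (Schwann cell) to 0.86 (pan-leukocyte), with 0.58 for extracellular matrix.

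Alternatives were DESeq2, limma-voom with and without sample weights, other scaling factors, other low-count filters, the replicate number as a block, 1 surrogate variable (sva 3.50.0), a fold threshold, a smaller gene universe and leaving out each mouse. A covariate for leukocyte content (the mean log2 CPM of the pan-leukocyte list), leaving out the 3 libraries with most leukocyte counts, the same covariate with an estimated correlation, DESeq2 on the edgeR-filtered genes and edgeR without robust estimation were added after seeing the data. The lanes could not be compared, since each column holds a whole mouse library. Figures were drawn with matplotlib 3.10.9.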

Results

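Bone marrow stromal cells from 4 SS and 4 SA mice were profiled by RNA sequencing, with 1 library per mouse. Total counts were 24797857, 27829565, 30305254 and 27780444 in SA replicates 1 to 4 and 25790675, 31117007, 30263136 and 30959748 in SS replicates 1 to 4. The design asks how the transcriptome of the mesenchymal stromal cells that support blood stem cells differs in sickle cell disease.

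The sort and the genotype were examined first. Pdgfra, which encodes the sorted antigen CD140a, was at 338 ± 148 CPM in SA and 423 ± 64.9 CPM in SS. Itgav, which encodes CD51, was at 330 ± 85.4 CPM in SA and 584 ± 182 CPM in SS (log2 fold change 0.82, SE 0.27, adjusted p = 0.695). Ptprc, which encodes the gated-out antigen CD45, was at 454 ± 334 CPM in SA and 202 ± 211 CPM in SS, and Pecam1, which encodes CD31, at 22.1 ± 17.2 and 9.60 ± 14.7 CPM. Pecam1 was at 31.4 CPM in SS replicate 1 and at most 4.77 CPM in the other SS libraries. Its log2 fold change ran from -3.25 to -0.59 with each mouse left out. Transcripts of the mouse adult globin genes, which the human genes replace in both genotypes, were few: Hba-a1 had 86 to 482 counts per library and Hbb-bt 9 to 153. Xist had 57347 counts in SS replicate 2 and at most 420 in any other library. The Y-linked gene Ddx3y was at 0.434 CPM in SS replicate 2 and at 79.3 CPM or more in the other 7. Kdm5d, Uty and Eif2s3y, also Y-linked, had 8, 17 and 7 counts in SS replicate 2 and at least 1069, 969 and 717 in the others. By these genes SS replicate 2 reads as female and the other 7 as male, although the labels give no sex. SS replicate 2 is also the only library with its set of date-like title numbers.

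Between genotypes, no single gene passed the edgeR test. The genes below are those that the naming rule gave in each direction. By DESeq2 each of them passed (adjusted p from 8.34e-09 for Dclk1 to 0.0288 for Tecr) except Gzme, which got no adjusted p. In the simulation 68 of 191 DESeq2 calls were false. Dclk1, a microtubule-associated kinase, was at 21.7 ± 7.68 CPM in SA and 118 ± 22.4 CPM in SS (log2 fold change 2.45, SE 0.31, adjusted p = 0.148). Fndc1, a fibronectin-domain protein, was at 31.2 ± 3.13 and 163 ± 73.2 CPM (2.39, SE 0.32, adjusted p = 0.148). Dkk3, of the Dickkopf family of secreted Wnt modulators, was at 28.4 ± 5.94 and 107 ± 36.3 CPM, and Mmp11, a matrix metalloproteinase, at 21.4 ± 4.19 and 105 ± 44.7 CPM (both adjusted p = 0.183). Enpep, an aminopeptidase that cleaves angiotensin II, had a log2 fold change of 2.10 (SE 0.35, adjusted p = 0.295). Gzme, a granzyme, had 0 counts in all 4 SA libraries and 177, 948, 174 and 153 counts in SS replicates 1 to 4. The SS mean was at least 121-fold higher against a floor of 3 counts per SA library (adjusted p = 0.229). Most of that mean came from SS replicate 2, at 34.3 CPM against 4.93 to 6.24 CPM in the other SS libraries.

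In the other direction, Angptl1, an angiopoietin-like secreted protein, was at 31.3 ± 10.2 CPM in SA and 2.29 ± 1.40 CPM in SS (log2 fold change -3.77, SE 0.64, adjusted p = 0.295). Zfp335, a zinc finger protein, had a mean of 37.7 CPM in SA and 12.1 CPM in SS (-1.64, SE 0.32, adjusted p = 0.411). Ikzf3 and Btla, both genes of lymphocytes, had log2 fold changes of -3.54 and -1.93, Lrrc8c, a subunit of volume-regulated anion channels, -1.06, and Tecr, a fatty acid elongation enzyme, -1.15, with adjusted p-values from 0.411 to 0.520. The naming rule took only genes without overlap, so by selection all 12 were higher, or lower, in each SS library than in each SA library. On GRCm38, Dclk1 lies on chromosome 3 (55242364 to 55539068), Fndc1 on chromosome 17 (7738569 to 7827302), Gzme on chromosome 14 (56117626 to 56120625) and Angptl1 on chromosome 1 (156838562 to 156861078), each annotated as protein-coding.

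edgeR called 0 of 17316 genes at an adjusted p under 0.05 (smallest 0.148), and 1209 had an unadjusted p under 0.05, 697 higher and 512 lower in SS, where 866 are expected by chance. The genotypes did not overlap for 677 genes, or 3.91% of those tested, where chance gives 2.86%. DESeq2 called 319 genes, 179 higher and 140 lower. Besides the leading genes, those called higher included Ptn, Thy1, Ly6a, Col3a1, Col4a2, Fbn1, Sod3, Lrp1, Stat2, Hif1a, Cdkn2b, Notch3, Heyl and Rgs5. Il34, Hbb-bt, Pax5, Igkc, Ighm, Il7r and Gp1ba were among those called lower. Limma-voom called 0, and edgeR with no low-count filter called 5 (Dclk1, Fndc1, Dkk3, Mmp11 and Gzme). Without SS replicate 1, edgeR called 1, Fndc1 (adjusted p = 0.0351), and 1948 genes had an unadjusted p under 0.05.

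**Figure D1:**
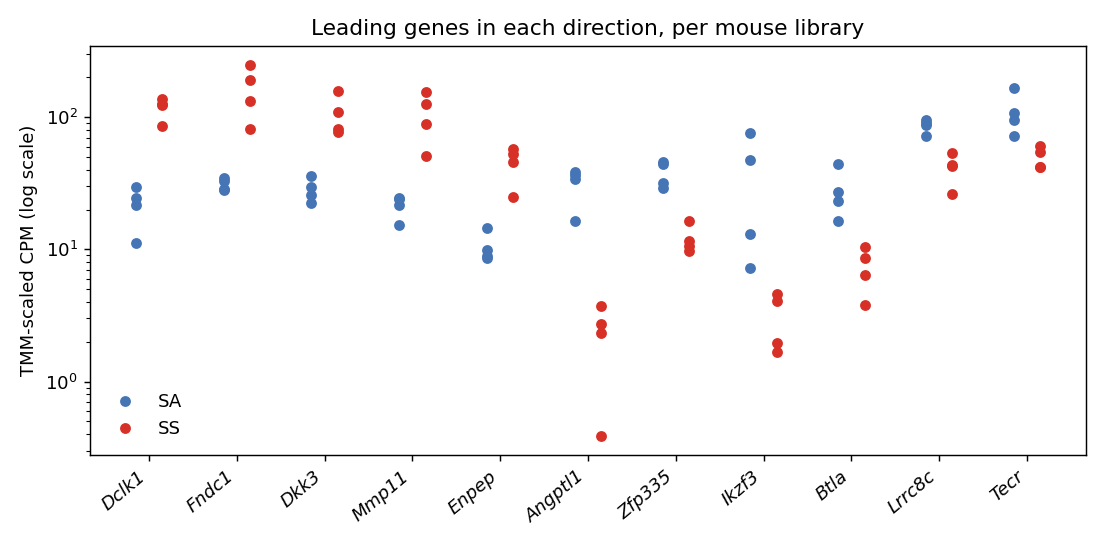
TMM-scaled CPM (log axis) of 11 of the 12 leading genes, with 1 point per mouse library, SA in blue and SS in red. By selection the points of the genotypes do not overlap for any gene, with Dclk1 at 21.7 CPM on average in SA and 118 in SS. Gzme is left out because its SA counts are 0.

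Factors that hold and feed blood stem cells were examined next. By edgeR none of them passed over all genes, and by DESeq2 Il34 and Ptn did (adjusted p = 0.0175 and 0.0261). Cxcl12, the chemokine that retains stem cells in marrow, was at 17989 ± 6379 CPM in SA and 18178 ± 3442 CPM in SS (log2 fold change 0.02, SE 0.29, adjusted p = 0.995). Its sign turned in 9 of the alternatives. Lepr, the leptin receptor that marks these stromal cells, was at 2042 ± 798 and 2160 ± 502 CPM (0.08, SE 0.31), with its sign turned in 6 alternatives. Kitl, stem cell factor, was at 867 ± 284 and 1180 ± 209 CPM (0.45, SE 0.26), Angpt1 at 119 ± 32.0 and 169 ± 66.6 CPM (0.50, SE 0.29) and the adhesion molecule Vcam1 at 897 ± 96.8 and 1080 ± 227 CPM (0.27, SE 0.20). With 1 mouse left out the values reached 0.28 for Kitl (SA replicate 2), 0.19 for Angpt1 (SS replicate 4) and 0.12 for Vcam1 (SS replicate 3). Tlr4, a receptor for endotoxin and heme, was at 64.9 ± 5.16 CPM in SA and 96.6 ± 31.2 CPM in SS, without overlap (0.57, SE 0.24, adjusted p = 0.695; 0.33 without SS replicate 3). Of 17 measured niche factors 13 were higher in SS (median log2 fold change 0.35, camera adjusted p = 0.235). Adjusted over the list alone, Igf1 (0.70), Ptn (3.39) and Il34 (-1.32) passed. Ptn was at 107 CPM in SS replicate 2 and 1.44 CPM in SS replicate 1, and its log2 fold change was 1.98 without SS replicate 2. The median of the niche list ran from 0.18 to 0.55 with each mouse left out. With the leukocyte covariate it was 0.12 and without the 3 leukocyte-rich libraries 0.20, both with the camera direction lower (adjusted p = 0.716 and 0.885). With that covariate Cxcl12 was at -0.19, Lepr -0.13, Kitl 0.19, Angpt1 0.15, Vcam1 0.24 and Tlr4 0.66. Cxcl12 was at 14866 and 10504 CPM in the leukocyte-rich SA replicates 1 and 2, and at 23454 and 23132 CPM in SA replicates 3 and 4.

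**Figure D2:**
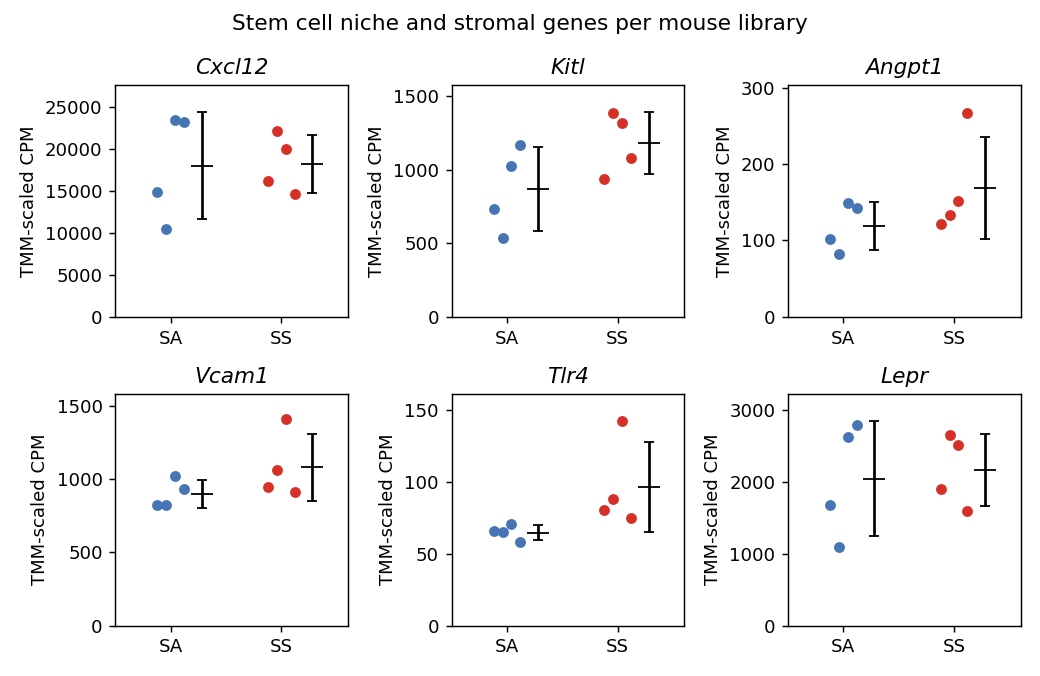
TMM-scaled CPM of 6 genes named in advance, with 1 point per mouse (SA blue, SS red) and the mean ± SD of 4 mice in black. Cxcl12 averages 17989 CPM in SA and 18178 in SS, and Tlr4 is the 1 gene of the 6 without overlap.

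Matrix and mural genes were higher in SS as groups. Of 33 extracellular matrix genes 32 were higher in SS (median log2 fold change 0.79, camera adjusted p = 8.8e-10). The call was lost with an estimated correlation (adjusted p = 0.615). Col3a1, a fibrillar collagen, was at 356 ± 117 CPM in SA and 1428 ± 661 CPM in SS, the basement membrane collagen Col4a2 at 126 ± 20.0 and 303 ± 117 CPM, and Fbn1, the microfibril protein fibrillin-1, at 1013 ± 314 and 2139 ± 295 CPM, all 3 without overlap. By edgeR no member passed over all genes, and 13 passed adjusted over the list alone. By DESeq2 all 3 passed over all genes (adjusted p = 0.000412 for Col3a1, 0.0130 for Col4a2 and 0.0208 for Fbn1). Mean leukocyte transcripts were lower in SS, although SS replicate 1 lay above SA replicates 3 and 4. With the pan-leukocyte score as a covariate the matrix median was 0.26, and without the 3 leukocyte-rich libraries it was 0.61. Of 13 pericyte and smooth muscle genes 12 were higher (median 0.96, camera adjusted p = 4.47e-05, and adjusted p = 0.615 with an estimated correlation). Rgs5, a pericyte regulator of G-protein signalling, was at 347 ± 112 and 1936 ± 2047 CPM and Notch3 at 76.7 ± 14.2 and 160 ± 36.4 CPM. Rgs5 reached 4998 CPM in SS replicate 4, and its log2 fold change was 1.40 without that library. 6 members of that list passed adjusted over the list alone. Its median was 0.53 with the leukocyte covariate and ran from 0.57 to 1.13 with each mouse left out. Without the 3 leukocyte-rich libraries its call was lost (adjusted p = 0.0584).

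3 further lists were higher in SS by camera, each with an adjusted p of at least 0.615 with an estimated correlation. Stromal identity genes had a median of 0.31 (16 of 20 higher, camera adjusted p = 0.0121), with Thy1 at 4.75 ± 2.98 and 28.2 ± 17.0 CPM and Ly6a at 10.6 ± 6.05 and 40.7 ± 28.5 CPM. Thy1 and Ly6a passed adjusted over the list alone. With the leukocyte covariate that median was 0.00101 and the call ended (adjusted p = 0.601), as it did without the 3 leukocyte-rich libraries (adjusted p = 0.641), and the median ran from 0.10 to 0.52 with each mouse left out. The call also ended without SA replicate 1 (camera adjusted p = 0.0615) and without SA replicate 2 (camera adjusted p = 0.242). Wnt, Notch and BMP genes had a median of 0.45 (24 of 33 higher, camera adjusted p = 0.00469), led by Notch3, its target Heyl (0.84) and Id3 (0.86). Notch3 passed adjusted over the list alone. With the covariate the list median was 0.21 and the call ended (adjusted p = 0.236), as it did without the 3 leukocyte-rich libraries (0.25, adjusted p = 0.641), and the median ran from 0.22 to 0.79 with each mouse left out. Omitting SA replicate 1 (camera adjusted p = 0.0504) or SA replicate 2 (camera adjusted p = 0.0768) also ended this call. Interferon response genes had a median of 0.28 (24 of 38 higher, camera adjusted p = 0.0265). Stat2 was at 60.1 ± 10.1 and 99.7 ± 11.4 CPM, Ifit1 at 18.5 ± 6.63 and 42.1 ± 8.11 CPM, and Ifi44 had a log2 fold change of 1.41. The interferon median ran from 0.12 to 0.39 with each mouse left out, and 4 of these 8 omissions ended the call. So did the replicate number as a block (camera adjusted p = 0.0519). The interferon call stayed with the leukocyte covariate (median 0.24, camera adjusted p = 0.00829), though not with an estimated correlation as well (adjusted p = 0.718). It also stayed without the 3 leukocyte-rich libraries (0.49, camera adjusted p = 0.0023).

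Osteogenic genes were lower as a group (14 of 23 lower, median -0.30, camera adjusted p = 0.0405, and adjusted p = 0.831 with an estimated correlation). Smpd3, a sphingomyelinase of bone matrix cells, was at 51.9 ± 43.8 CPM in SA and 8.47 ± 6.90 CPM in SS, and Bglap2, an osteocalcin gene, at 41.3 ± 35.9 and 9.71 ± 10.2 CPM. Tnfsf11, which encodes RANKL, went the other way, at 24.5 ± 15.3 and 72.3 ± 47.6 CPM. With the leukocyte covariate the osteogenic median was -0.98, and without the 3 leukocyte-rich libraries -0.65 (camera adjusted p = 0.000242). The median ran from -0.57 to -0.10 with each mouse left out, where 5 of 8 omissions ended the call. With the replicate number as a block the call also ended (camera adjusted p = 0.0519). Tnfsf11 was at 0.99 without SS replicate 2 (1.56 with it), and Bglap2 ran from -3.16 without SS replicate 2 to -1.39 without SA replicate 3. Cell cycle genes were lower in 29 of 30 cases (median -0.61, camera adjusted p = 2.6e-06, and adjusted p = 0.615 with an estimated correlation), among them Ube2c (-0.88), Pcna (-0.63) and Rrm2 (-0.61), with a median of -0.27 with the covariate and from -0.75 to -0.39 with each mouse left out. Without the 3 leukocyte-rich libraries it was -0.11 and the call ended (adjusted p = 0.618). Replication-dependent histone genes, which share reads between copies, had a median of -0.54 (camera adjusted p = 1.59e-05, and adjusted p = 0.615 with an estimated correlation), including Hist1h4d (-0.86), Hist1h4c (-1.12) and Hist1h2bh (-1.14). With the covariate their median was -0.10 and the call ended (adjusted p = 0.236), as it did without the 3 leukocyte-rich libraries (-0.00836, adjusted p = 0.618). The median ran from -0.74 to -0.24 with each mouse left out, with Hist1h4d at -0.53 without SA replicate 2.

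Markers of 7 groups of blood cell genes were lower in SS, unevenly between libraries, while the macrophage and the stem and progenitor lists did not pass (camera adjusted p = 0.963 and 0.538). All 18 measured B cell genes were lower (median -2.96, camera adjusted p = 8.8e-10, and adjusted p = 0.615 with an estimated correlation), with Pax5 at 49.4 ± 39.0 and 3.75 ± 3.46 CPM, Ighm at 383 ± 421 and 36.7 ± 31.8 CPM and Igkc at a log2 fold change of -3.96 (-2.17 without SA replicate 1). 7 members passed adjusted over the list alone. With the leukocyte covariate the B cell median was -1.25 and without the 3 leukocyte-rich libraries -1.63. All 23 neutrophil genes (median -1.39), 11 megakaryocyte genes (-2.38) and 15 pan-leukocyte genes (-1.18) were lower, with camera adjusted p-values of 4.09e-08, 0.000997 and 4.47e-05 (adjusted p = 0.615 for each with an estimated correlation). With each mouse left out, the neutrophil median went as low as -2.24 (-0.24 with the covariate), and the pan-leukocyte median ran from -2.01 to -0.81. Both lists stayed lower without the 3 leukocyte-rich libraries, at -0.78 and -0.61 (camera adjusted p = 0.00107 and 0.0084). Without the 3 leukocyte-rich libraries the megakaryocyte median turned to 0.0975, with Pf4 at 0.20 and Ppbp at 2.55, and the call ended (adjusted p = 0.818). That call also ended with the covariate (-1.03, adjusted p = 0.0803) and without SA replicate 2 (adjusted p = 0.0528). The granule genes Ngp (2785 ± 2032 and 853 ± 826 CPM) and Ctsg (-1.52), the platelet genes Gp1ba (-4.25), Pf4 (-3.30) and Ppbp (-4.10), and the leukocyte genes Cd52 (-1.45), Was (-1.37) and Arhgdib (-1.20) are examples. With each mouse left out Pf4 ran from -4.09 to -2.00 and Ppbp from -5.41 to -2.54. Over the same omissions Ngp ran from -2.57 to -1.28 and Was from -2.08 to -1.02. T and NK cell (median -0.41), erythroid (-0.33) and mouse globin (-0.94) lists were also lower, with camera adjusted p-values of 0.0318, 0.0154 and 0.0127. With an estimated correlation none of the 3 passed (adjusted p = 0.615, adjusted p = 0.741 and adjusted p = 0.615). The T and NK median ran from -0.65 to -0.15 and the erythroid median from -0.60 to -0.09 with each mouse left out, and 5, 3 and 3 of the 8 omissions ended the T and NK, erythroid and globin calls. The covariate took these medians to -0.05, 0.14 and -0.24 and ended the calls (adjusted p = 0.738, 0.443 and 0.362). All 3 were also lost without the 3 leukocyte-rich libraries (adjusted p = 0.641 for each). Il7r (-2.84), Nkg7 (-1.35) and Cd28 (-1.05) led the first, Car1 (-0.96), Tspo2 (-1.06) and Aqp1 (-0.76) the second, and Hbb-bt (-2.58) the third. With each mouse left out Car1 ran from -1.56 to -0.66, Tspo2 from -1.29 to -0.71 and Aqp1 from -1.06 to -0.48.

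Measured as summed CPM per library, neutrophil transcripts were at 23184 ± 16437 in SA and 8422 ± 8629 in SS (exact permutation p = 0.2, adjusted p = 0.457, n = 4 per genotype). The range ran from 1468 (95% Wilson interval 1455 to 1482) in SS replicate 4 to 39522 (39449 to 39594) in SA replicate 2. Pan-leukocyte transcripts were highest in SA replicates 1 and 2 (4520 and 5025) and SS replicate 1 (3131). B cell transcripts were at 786 ± 759 and 87.2 ± 87.8 (exact permutation p = 0.0571). Pericyte transcripts were at 1091 ± 130 and 3319 ± 2656, higher in each SS library than in each SA library (exact permutation p = 0.0286, the smallest this design gives, adjusted p = 0.457). SS replicate 4 was at 7293 and the other SS libraries at 1749 to 2192. Mitochondrially encoded transcripts took 19.4 ± 1.44% of counts in SA and 21.3 ± 2.70% in SS (exact permutation p = 0.257). None of the 16 measures passed adjustment, which this design allows only if about 10 of them reach the smallest p together.

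**Figure D3:**
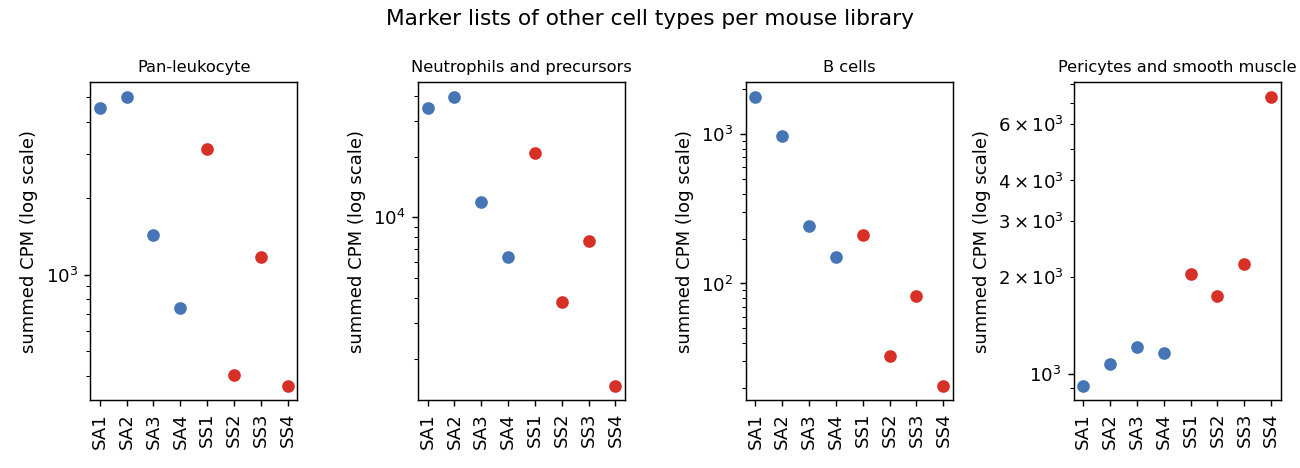
Summed CPM (log axes) of 4 marker lists, 1 point per mouse library, SA in blue and SS in red. Pan-leukocyte values are highest in SA replicates 1 and 2 and SS replicate 1, and pericyte values lie between 916 and 1213 in SA and between 1749 and 7293 in SS.

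The functions most often tied to sickle disease did not pass as lists with genotype alone in the model. Heme and iron genes had a median of 0.19 (camera adjusted p = 0.538), with Lrp1, a receptor for hemopexin-bound heme, at 515 ± 122 and 1165 ± 285 CPM and passing adjusted over the list alone, Aco1 at 0.56 and Lcn2, a neutrophil granule gene as well, at -1.74. Lcn2 was at -0.59 with the leukocyte covariate and -2.96 without SS replicate 1, and the list median ran from -0.05 to 0.19 with each mouse left out. Antioxidant genes had a median of 0.03 (adjusted p = 0.992), with Sod3 at 12.5 ± 8.99 and 45.3 ± 22.5 CPM, Gpx8 at 0.82 and Gsr at -0.86. That median ran from -0.08 to 0.12 with each mouse left out. Genes for sources of reactive oxygen had a median of -1.03 (adjusted p = 0.354), with Nox4 at 1.82 and Cyba, an oxidase subunit abundant in leukocytes, at -1.15. The reactive oxygen median ran from -1.77 to -0.58 with each mouse left out and was 0.11 with the leukocyte covariate, where Cyba was at -0.24. Nuclear respiratory chain genes had a median of -0.06 (adjusted p = 0.538; Uqcrfs1 0.87, Sdhb 0.62, Ndufa1 -0.47), and mitochondrial quality genes 0.16 (adjusted p = 0.838; Ucp2 -0.92). With each mouse left out these medians ran from -0.12 to 0.07 and from 0.02 to 0.23. Uqcrfs1 was at 0.46 without SS replicate 3, Sdhb at 0.41 without SS replicate 2 and Ucp2 at -0.54 without SA replicate 2. Toll-like receptor and NF-kB genes had a median of 0.01 (adjusted p = 0.977), with Myd88 at 33.5 ± 10.2 and 16.4 ± 4.65 CPM and Cxcl1 at 1.52. That median ran from -0.14 to 0.19 with each mouse left out. With the leukocyte covariate the respiratory chain list was called lower (-0.23, camera adjusted p = 0.000158) and the Toll-like receptor list higher (0.47, camera adjusted p = 0.0330). Neither was called with an estimated correlation as well (adjusted p = 0.526 and 0.718). Without the 3 leukocyte-rich libraries neither was called (adjusted p = 0.818 and 0.641).

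Hypoxia and glycolysis genes had a median of 0.05 (camera adjusted p = 0.838), although Hif1a was at 126 ± 7.32 and 202 ± 28.5 CPM without overlap. P4ha2 was at 1.13 and Slc2a1 at -0.92 on the log2 scale. Slc2a1 turned sign in 3 alternatives and was at 0.03 with the leukocyte covariate, and P4ha2 was at 0.70 without SS replicate 2. The hypoxia median ran from -0.15 to 0.08 with each mouse left out. Unfolded protein response genes had a median of 0.34 (17 of 22 higher, adjusted p = 0.0711), with the chaperones Hyou1 (0.71), Calr (0.65) and Pdia3 (0.52). Complement and coagulation genes had a median of 0.36 (adjusted p = 0.0746), with C1s1, a complement protease, at 0.73 and F3, tissue factor, at 1.14. F3 ran from 0.84 without SA replicate 1 to 1.88 without SA replicate 4. With each mouse left out, the complement and coagulation median ran from 0.13 to 0.54 and the unfolded protein median from 0.18 to 0.35. Adipogenic genes had a median of 0.20 (adjusted p = 0.174), with Fabp4 at 2.08, Pparg at 0.87 and Cebpa at 0.62. Fabp4 was at 359 CPM in SS replicate 4, and its log2 fold change was 0.67 without that library, while Cebpa was at 0.38 without SS replicate 2. Senescence genes had a median of 0.03 (adjusted p = 0.731), with Cdkn2b at 5.16 from under 1 CPM in SA and Trp53inp1 at -0.85, and a range of the median from 0.00238 to 0.19 with each mouse left out. Cdkn2b ran from 3.63 without SS replicate 4 to 7.99 without SA replicate 1. Chondrogenic genes had a median of 0.72 (adjusted p = 0.538), with Col10a1 at 4.66, Cilp2 at 3.08 and Prg4 at -0.83. Col10a1 had 9185 counts in SS replicate 2 and 15, 53 and 168 in the other SS libraries, and its log2 fold change was -0.36 without SS replicate 2. Prg4 ran from -1.33 to -0.55. The chondrogenic median ran from 0.03 to 1.02 with each mouse left out.

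Macrophage (median -0.12), stem and progenitor (-0.26), endothelial (0.34), skeletal muscle (-0.29) and Schwann cell (0.87) lists did not pass, with camera adjusted p-values from 0.317 to 0.992. Their leading genes were Ms4a7 (2.56), Myb (-1.64), Flt4 (1.25), Myl1 (1.47) and Ngfr (4.18). Myl1 was at -0.44 and Ngfr at 2.37 without SS replicate 4, and Flt4 at 0.55 without SS replicate 1. With each mouse left out the medians ran from -0.43 to 0.61 (macrophage), -0.49 to 0.07 (stem and progenitor), -1.22 to 0.86 (endothelial), -1.74 to 0.21 (skeletal muscle) and 0.29 to 1.16 (Schwann cell). Immediate early (-0.06, led by Cyr61 at 1.07), mitochondrially encoded (0.11), ribosomal protein (0.04, led by Rpl30 at -0.33), nuclear-retained (-0.30) and sex-linked (-0.49) lists did not pass either (adjusted p from 0.386 to 0.897). With each mouse left out their medians ran from -0.24 to 0.10, -0.02 to 0.21, -0.06 to 0.19, -0.43 to -0.20 and -0.83 to -0.08. Xist, set by SS replicate 2, passed adjusted over each of the last 2 lists alone, and so did Meg3 over the nuclear-retained list. In the lists for which no such count is given, 0 genes passed adjusted over the list alone. The camera direction was opposite to the sign of the median for the skeletal muscle, ribosomal protein, mitochondrially encoded and Toll-like receptor lists. The mean and the median differed in sign for the macrophage, antioxidant, mitochondrially encoded, nuclear-retained and sex-linked lists. 15 of the 38 lists passed by camera with the preset correlation, 5 higher and 10 lower, 0 with an estimated correlation and 0 by fry (smallest adjusted p = 0.406). Without the 3 libraries with most leukocyte counts 6 passed, and without SA replicate 2 there were 9. With the preset correlation the matrix, B cell and neutrophil calls stayed in every setting run.

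**Figure D4:**
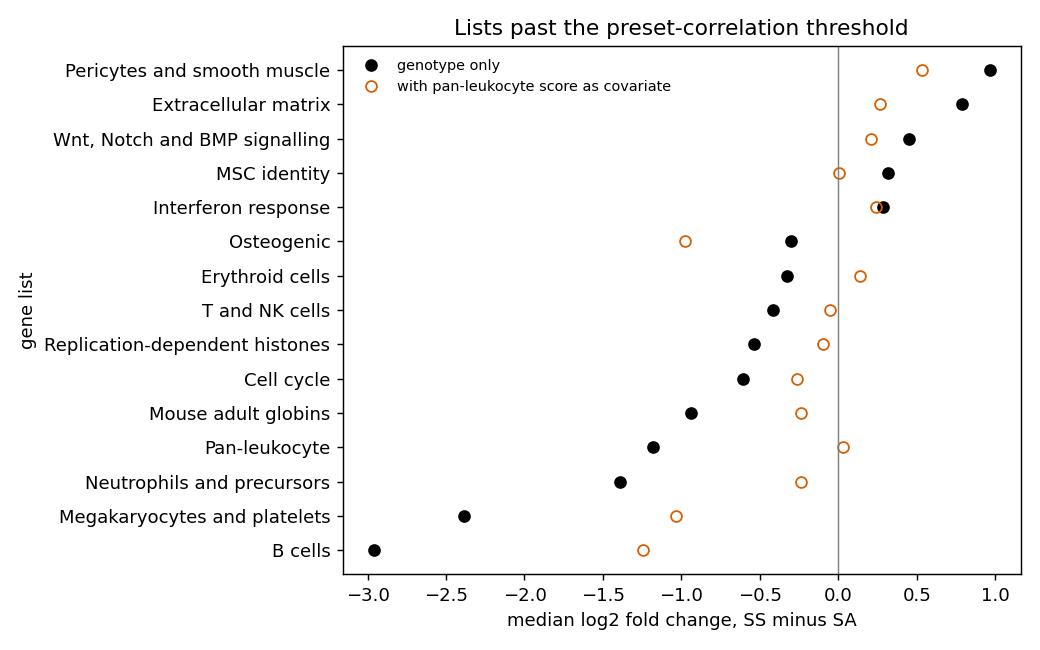
Median log2 fold change (SS minus SA) of the 15 lists called with the preset correlation, without (filled) and with (open) the pan-leukocyte score as a covariate. The matrix median goes from 0.79 to 0.26 and the osteogenic median from -0.30 to -0.98.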

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

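Of the tests in this part, the leukocyte covariate, the comparison of stromal lists and the carry-over correlations were chosen after related values had been seen. The omission of the 3 leukocyte-rich libraries and DESeq2 on the edgeR-filtered genes were also added after seeing the data. The other tests were set beforehand. Single libraries far from the other 3 of their genotype were found in 26 of 342 comparisons of the gap to the nearest library with the range (about 17.1 by chance), 11 of them in SS replicate 2.

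In log2 CPM, SS replicate 2 stood apart for Ddx3y (-0.99), Kdm5d (-1.47), Uty (-0.54) and Eif2s3y (-1.63), and for the sex-linked list (mean 1.28) and the nuclear-retained list, which holds Xist (5.90). It was highest of the SS libraries for Gzme (5.10), Tnfsf11 (7.17) and Sdhb (5.96), and lowest for Myb (3.77) and the histone list (0.73). SS replicate 1 was lowest for Tfb1m (2.62), Gpx8 (6.76) and Calr (8.21) and for total counts (25790675, or 25.8 M), and highest for the endothelial list (mean log2 CPM 3.50, summed CPM 314). SS replicate 4 had the highest pericyte sum (7293 CPM) and the lowest Tspo2 (1.83). SA replicate 1 was lowest in SA for Stat2 (5.50), Ifit1 (3.12) and P4ha2 (1.31), SA replicate 2 for Angptl1 (4.04), and SA replicate 4 for Hbb-bs (-0.87), Eif2s3y (4.73) and Was (3.64).

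The matrix list was higher in SS (median log2 fold change 0.79). SS replicate 2, the library with high Xist, does not account for it, since the median was 0.67 without that library. Less blood-cell RNA in the SS libraries may account for part of it, since with the leukocyte covariate the median was 0.26 (0.24 to 0.44 with each library left out; camera adjusted p = 0.00829, and adjusted p = 0.718 with an estimated correlation), but the median was 0.61 without the 3 leukocyte-rich libraries (adjusted p = 0.000136, not run with an estimated correlation). Whether the matrix list moved further than other stromal lists cannot be told apart from an equal shift, because the exact permutation p of the difference was 0.257 against the stromal identity and adipogenic lists and 0.0286 once the osteogenic list, already known to be lower, was added. Chance cannot be excluded, since 3 of the 35 splits of the 8 libraries, the real one among them, gave as large a median (real 0.79, highest other 1.0025). The other splits that did so put SA replicates 1 and 2 with SS replicate 1, the 3 leukocyte-rich libraries. This count therefore does not measure chance apart from leukocyte content. The genotype itself remains an untested biological explanation.

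Blood-cell lists were lower in SS although the gate removes CD45 and Ter119 positive cells. Carry-over that varies from library to library may contribute: with the genotype means removed, the list scores correlated with the pan-leukocyte score at 0.92 for neutrophils, 0.95 for B cells and 0.86 for erythroid genes, but at 0.50 for megakaryocyte genes. That last value lies between the bounds set for the test. With the genotype means removed, these correlations hold no information on the difference between genotypes. At no value could they have told carry-over and a genotype difference apart. The B cell list stayed lower with the leukocyte covariate (median -1.25, camera adjusted p = 2.44e-05, and adjusted p = 0.480 with an estimated correlation) and without the 3 leukocyte-rich libraries (-1.63). The neutrophil median was -0.24 with the covariate (camera adjusted p = 0.0428, and adjusted p = 0.781 with an estimated correlation). Without the 3 leukocyte-rich libraries it was -0.78 (camera adjusted p = 0.00107, not run with an estimated correlation). The neutrophil list summed to 39522 CPM in SA replicate 2 and 1468 CPM in SS replicate 4.

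DESeq2 called 319 genes where edgeR called 0. Genes read in only some libraries may contribute, since 35.4% of the called genes (95% exact interval 30.2 to 40.9) had a 0 count in at least 1 library, against 20.2% of all genes given an adjusted p. The called genes were also less abundant (median of mean CPM 4.48 against 9.20), so zeros cannot be separated from low expression. The edgeR filter dropped 86 of the 319 called genes. Of the 233 that edgeR tested, 228 had an edgeR unadjusted p under 0.05, on the same counts (smallest edgeR adjusted p = 0.148). On the edgeR-filtered genes DESeq2 still called 129. In the simulation 68 of 191 DESeq2 calls were false, against 1 of 81 by edgeR. Chance cannot be excluded, since 6 of the 35 splits gave as many DESeq2 calls, the highest other being 1589, and 6 gave as many genes at an unadjusted p under 0.05 (real 1209, highest other 2630). Each count includes the real split. Every other split that reached these 2 values put SA replicates 1 and 2 with SS replicate 1, the leukocyte-rich libraries. The remaining splits gave at most 138 DESeq2 calls and 935 such genes (SA replicates 1 to 3 with SS replicate 3). These counts therefore do not measure chance apart from leukocyte content. For the number of lists called, 7 of 35 did, the real split included (real 15, highest other 25). The split of SA replicates 1 to 3 and SS replicate 1 against the rest gave 115 edgeR calls and the highest DESeq2 count, which points to a structure of the samples: those 4 libraries have the highest pan-leukocyte sums.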

How the results depend on the processing

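The leukocyte covariate with either correlation, the omission of 3 libraries, DESeq2 on edgeR-filtered genes and edgeR without robust estimation were chosen after seeing the data. The count of 0 genes became 319 with DESeq2, 129 with DESeq2 on the edgeR-filtered genes and 5 with no low-count filter, and ran from 0 to 1 with each mouse left out (1 without SS replicate 1). The 1209 genes at an unadjusted p under 0.05 became 2407 with DESeq2, 3122 with no filter and 592 against a fold of 1.5, whose stricter null lowers the count by construction, and ran from 897 to 1948 with each mouse left out. The 15 lists became 0 with an estimated correlation, 0 by fry, 0 with the leukocyte covariate and an estimated correlation, and 6 without the 3 leukocyte-rich libraries (fewer samples), and ran from 9 to 15 with each mouse left out. Among lists called before or after the change, the camera direction turned with the leukocyte covariate for Toll-like receptor and NF-kB (median 0.47), macrophage (1.34), erythroid (0.14) and, by construction, pan-leukocyte genes (0.0304), and without the 3 libraries for megakaryocyte genes (0.0975). Medians also turned sign with the covariate for reactive oxygen (0.11), stem and progenitor (0.32), ribosomal protein (-0.30), mitochondrial quality (-0.04), mitochondrially encoded (-0.07), antioxidant (-0.10) and immediate early genes (0.08), and without the 3 libraries for macrophage (1.14), skeletal muscle (0.46), respiratory chain (0.02) and antioxidant genes (-0.04). The ribosomal protein list ran from -0.0580 to 0.192 with each mouse left out and its camera direction turned from lower to higher at 0.192 without SS replicate 1. Beyond the constructions named, the cause was not tested. With the replicate number as a block, 0 genes passed, 1255 had an unadjusted p under 0.05 and 13 lists passed. The interferon and osteogenic calls were lost (camera adjusted p = 0.0519 for each). Same-numbered mice deviated together with correlations of 0.22, -0.15, -0.02 and 0.14, and not every mouse correlated best with its own number, so the numbers do not pair them. The direction changed in 65 of 646 list values, 38 of 2877 gene values and 7 of 144 composition values. Lanes were not run, as each column holds both. At this spread between mice, simulated 2-fold changes were recovered in 2% of cases by edgeR and 14% by DESeq2, so most changes of that size would be missed.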

Other observations

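The gene and list values in this part come from the leukocyte covariate, chosen after seeing the data, and its genes were picked after their values were seen. No gene passed in that fit. The smallest adjusted p belonged to Dmp1, a matrix protein of osteocytes, at 78.6 ± 58.2 CPM in SA and 33.3 ± 26.0 CPM in SS (log2 fold change -2.69, SE 0.30, edgeR adjusted p = 0.0509). Ibsp, bone sialoprotein, had a value of -1.45 and Smpd3 of -3.20, and Creb3l1, a transcription factor of collagen-secreting bone cells, of -1.35. The osteogenic list median was -0.98 (camera adjusted p = 6.15e-09 with the preset correlation, and adjusted p = 0.480 with an estimated correlation). The osteogenic scores of SA replicates 3 and 4 were 7.71 and 7.66, against 6.05 and 6.43 in SA replicates 1 and 2 and 5.71 to 7.13 in SS.

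In the same fit, respiratory chain (-0.23) and ribosomal protein (-0.30) lists were lower in SS by camera with the preset correlation, and macrophage (1.34), endothelial (1.17) and Toll-like receptor (0.47) lists were higher. None passed with an estimated correlation (adjusted p from 0.480 to 0.718 for the 5 lists). The endothelial score was 3.50 in SS replicate 1 and 0.37 to 0.51 in the other SS libraries. Without the 3 leukocyte-rich libraries none of these 5 was called, and the ribosomal protein and respiratory chain medians were 0.06 and 0.02. Rsad2, an interferon-induced antiviral gene, was at 151 ± 130 CPM in SA and 164 ± 154 CPM in SS, with a log2 fold change of 1.75 with the covariate and 0.12 without it. Adgre1, the macrophage antigen F4/80, had a value of 2.88, against 1.38 without the covariate (edgeR adjusted p = 0.249 for Rsad2 and 0.343 for Adgre1). Dclk1 and Fndc1 had values of 2.15 and 2.23, and Col3a1 of 1.84.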
